A study of Mus musculus with 16 samples.

How the data were processed

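The series measured H3K27me3 by ChIP-seq in mouse embryonic stem cells grown on gelatin in serum medium with LIF and the inhibitors PD0325901 and CHIR99021, per the labels' protocols. Cells were fixed with formaldehyde, chromatin was sheared by sonication, and libraries were made from antibody-bound and input DNA, per the labels' protocols. The 16 libraries were 8 H3K27me3 and 8 input libraries, 1 of each for 2 backgrounds (WT and Firre KO), 2 transgene states and 2 times (0 and 48 h of doxycycline), so that 4 lines were each seen at 2 times. Groups were taken from the genotype, antibody and time labels.

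The deposited count table gave whole-number read counts per consensus peak and library without normalisation. The deposited peak list gave for each peak a score, which at nearly all peaks equals 10 times the −log10 q-value written as a whole number, a fold enrichment by the peak caller and −log10 q-values. These values of the authors describe the peak and not a library. The submitters' processing notes name BWA 0.7.17-r1188, MACS2 2.2.71, featureCounts, DESeq2 1.26.0 and the build mm10 without order or role. Which libraries entered the peak call is not given in the sources used here, and the peak identifiers in the deposited list refer to 1 combined set. Counts from broad regions of differing width cannot show changes narrower than a peak, and calling peaks on some libraries only would favour regions strong in those. All 102957 peaks occurred in both tables, and 137 lay on 29 scaffolds. Peak starts are printed as deposited, since the table does not say whether they count from 0 or 1.

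Peaks were assigned to genes with a RefSeq table of the assembly GRCm38.p6, which is the same build as mm10. The table holds gene spans without strand, exons or UTRs, so the planned window around start sites was replaced by the gene span with 2000 bp on either side, and exonic or intronic position is not reported. This gave 18364 regions for 20261 genes, where genes with the same peaks share 1 region. Neighbouring genes can share peaks, so their values are not independent.

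The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the counts with TMM factors, filterByExpr and Benjamini-Hochberg adjustment at 0.05. Induction was the transgene by time term beside line and time (2 residual degrees of freedom), time was tested beside line (3), and background and transgene in an additive model with time (4). Log2 values are given ± SE of the fit. H3K27me3 against input used total counts and the condition as block. The same models were run on the input libraries. Gene lists fixed before the data were examined were Hox, neuroectoderm, mesoderm and endoderm regulators, pluripotency, housekeeping, Polycomb, imprinted, germline, X inactivation, Firre neighbour and Firre contact genes, and fibroblast, primitive endoderm, trophoblast and primed epiblast markers. Lists were tested per region, over all regions and over the list alone, and as sets with camera (limma 3.58.1). Shares per chromosome were compared by exact two-sided permutation of 4 against 4 libraries, which takes both times of a line as separate. Intervals of counts are 95% exact Poisson intervals, and those of ratios of counts come from 95% exact binomial intervals. Named peaks, by a rule set before the data were examined, were the 12 largest rises and 12 largest falls among peaks past the threshold, above the median depth and in the same direction in every matched pair, and also the Firre peak, the list members past the threshold over the list alone and the Hox clusters. Of peaks named without coordinates, only the gene they overlap is given. Some list members are not reported here.

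Libraries of the same line at 0 and 48 h differed little beyond sampling noise (chi-square per degree of freedom 1.00 to 1.01 in input and 1.04 to 1.12 in H3K27me3, against 1.02 to 1.33 and 1.12 to 2.03 between lines). Since the times are separate conditions, none were merged. The replicate number is 1 in every group and pairs no samples; libraries were matched by line. On simulated counts with 200 changed peaks, the time model recovered 65 of 100 at a log2 change of 0.5 and 98 of 100 at 1, the background model 66 and 100, the transgene model 59 and 97, and the induction model 13 and 46, with 7, 7, 10 and 2 false calls. In these simulations changes were placed only in peaks above a minimum mean count, and no differences between lines were simulated. The false calls thus do not carry over to the background and transgene models in the real data, where lines differ. The enrichment model recovered 120 of 200 at 0.5 among 19973 peaks. Alternatives were other scaling factors, DESeq2 1.42.0 and limma-voom, a minimum mean count of 50, input as an offset, peaks at least 2-fold over input, other designs, wider windows and each library left out. The filterByExpr step kept all 102957 peaks, so dropping it was no test. Added after the data were seen were a robust dispersion, an offset that follows enrichment, windows at the gene ends, an exchange of whole lines for the share of chromosome 11, the Firre neighbour list without Firre, and analyses without chromosome 11 or without the line labelled KO control. Python 3.11.15 with SciPy 1.17.1 was used for the remaining steps.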

Results

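H3K27me3, the histone mark deposited by Polycomb repressive complex 2 at silenced developmental genes, was profiled by ChIP-seq in mouse embryonic stem cells in which the long non-coding RNA Firre could be induced with doxycycline. The labels gave 4 cell lines: WT cells (WT control), WT cells with an inducible Firre transgene (WT transgene), cells labelled Firre KO (KO control) and Firre KO cells with the inducible transgene (KO transgene). Each line was sampled at 0 h and 48 h of doxycycline. Every condition had 1 H3K27me3 library and 1 input library, which made 8 and 8 libraries and left no replicate of any single condition. Total counts over the consensus peaks ran from 10380781 to 14787938 in H3K27me3 and from 3340654 to 6244333 in input, the lowest of each being the KO control library at 0 h. Tests therefore compared groups of libraries across lines and times. The p-values measured only a spread in these libraries that was pooled over peaks and may be technical, since no label gave separate cultures or clones. In the peak fits the prior degrees of freedom were infinite for induction, 1856 for time and 132 for background and transgene. The 2 or 3 residual degrees of freedom of a peak thus carried almost no weight for induction and time. With a common dispersion of 9.8e-05 in these 2 fits, the SEs and p-values mostly follow read depth.

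The consensus set held 102957 regions with a median width of 2356 bp. The highest fold enrichment by the peak caller, 4.85, lay over HoxB. The Hox clusters are arrays of homeobox genes that pattern the body axis. Over the 8 conditions, counts over input were 2.36 ± 0.194-fold (SD, n = 8) at HoxA (chromosome 6, 52139636 to 52282771), 2.13 ± 0.122-fold at HoxB (chromosome 11, 96161307 to 96387596), 2.03 ± 0.261-fold at HoxC (chromosome 15, 102887393 to 103040609) and 2.13 ± 0.130-fold at HoxD (chromosome 2, 74637183 to 74789361; all mm10). All 39 listed Hox genes, all 24 neuroectoderm regulators and all 24 mesoderm regulators had a peak within 2 kb of the gene, against 3 of 20 pluripotency genes and 2 of 18 housekeeping genes. The median region was 1.73 ± 0.0579-fold over input for neuroectoderm, 1.54 ± 0.0594-fold for mesoderm and 1.40 ± 0.0381-fold for endoderm regulators, and 0.973 ± 0.00571-fold over all 18364 gene regions (SD, n = 8). Against the matched input, edgeR's quasi-likelihood test called 7988 peaks higher and 37014 lower after Benjamini-Hochberg adjustment at 0.05 with total counts as library sizes, and 14224 higher and 10097 lower with TMM scaling. At least 2-fold enrichment was reached by 127 peaks. Library sizes were counts within the consensus peaks, so a ratio of 1 is the average over these peaks and not the genomic background. A peak called lower than input can thus still carry H3K27me3. The peak caller's own fold had a median of 1.53 over all peaks.

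The Firre locus was examined as a check on the labels. The Firre gene (chromosome X, 50563120 to 50635321) held 1 peak of 949 bp (50569315 to 50570264), with 1 and 0 H3K27me3 counts in the WT control line at 0 h and 48 h, a count of 0 allowing up to 3 by the one-sided and 3.69 by the two-sided 95% exact Poisson limit. In the WT transgene line the count was 263 at 0 h and 57 at 48 h, in the KO transgene line 172 and 47, and in the line labelled KO control 164 and 177. Input over this peak with both times summed, relative to the mean of all chromosome X peaks per width, was 0.694 (95% exact Poisson interval 0.317 to 1.32) in WT control, 15.0 (13.0 to 17.3) in WT transgene, 10.7 (8.99 to 12.7) in KO transgene and 11.1 (9.15 to 13.4) in the line labelled KO control. The last value goes against a line with neither the gene nor a transgene, and that line is named here as the line labelled KO control. WT control held almost no H3K27me3 counts here without a lack of input. The counts in the other lines thus go with the extra Firre sequence and cannot be read as a mark on the chromosome X gene. No peak with a mean of 20 or more counts in WT was at 0 in all 4 KO libraries, and the deleted segment is not given in the sources used here, so the peak checks Firre copies and not the deletion. Intervals cover counting error only, because PCR copies are not independent molecules.

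**Figure D1:**
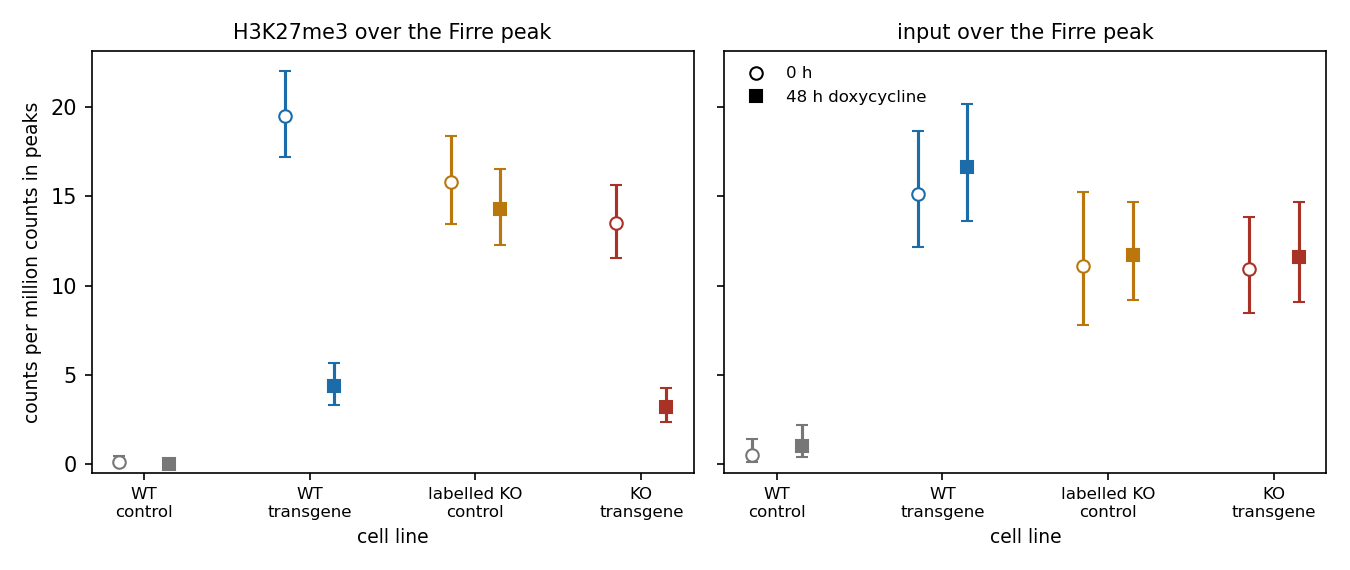
CPM over the Firre peak for H3K27me3 (left) and input (right) in each line at 0 h (open circles) and 48 h (filled squares), 1 library per point with 95% exact Poisson intervals. Input stayed level over time in the 3 lines with extra Firre sequence, while H3K27me3 dropped in both transgene lines.

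Induction of Firre was assessed as the 48 h against 0 h change in transgene lines minus the change in lines labelled without it, with the WT and KO backgrounds as the 2 measurements. In the KO background the comparator was the line labelled KO control, whose Firre input was 11.1 times the chromosome X mean. The contrast there is thus not between lines with and without extra Firre sequence. H3K27me3 fell at 6 peaks by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and no peak rose. Only 1 of the 6 was called higher than input and none reached 2-fold. The log2 ratio over input was 0.37 at Cdh3, 0.04 at Rapgef4, -0.04 at Shf, -0.19 at Il9r, -0.20 at Duox1 and -0.24 at Firre. These ratios are relative to the average consensus peak. The peak caller's fold was 2.44 at Cdh3, 2.02 at Rapgef4, 1.89 at Firre, 1.82 at Il9r, 1.79 at Shf and 1.71 at Duox1. The longest was a 23.8 kb domain (chromosome 2, 71968482 to 71992280; log2 difference of changes -0.86 ± 0.08 SE) over the start of the span of Rapgef4, which encodes a cAMP-activated exchange factor for Rap GTPases, touching the end of the lncRNA Gm39845. The domain's 48 h over 0 h ratio was 0.563 (95% interval 0.501 to 0.632) in WT transgene and 0.510 (0.453 to 0.575) in KO transgene, against 0.945 (0.854 to 1.05) in WT control and 1.02 (0.912 to 1.13) in the line labelled KO control. The other calls lay in Firre (-1.97 ± 0.22), in Duox1, a dual oxidase gene (chromosome 2, 122345775 to 122348081; -1.98 ± 0.27), in Shf (chromosome 2, 122366727 to 122368440; -1.74 ± 0.31), in Il9r, the interleukin 9 receptor gene (chromosome 11, 32188194 to 32203886; -0.59 ± 0.10), and in Cdh3, which encodes P-cadherin (chromosome 8, 106504389 to 106514850; -0.48 ± 0.10, adjusted p = 0.0348 by edgeR). At the 5 peaks other than Firre, both transgene lines fell below the control line of their background. The Firre call rests on counts that go with the extra Firre sequence and cannot be read as a change at the chromosome X gene. Shf was below the depth limit of the naming rule and was named after its value was seen.

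Input counts over the Rapgef4, Il9r, Cdh3 and Firre peaks differed by 0.01 ± 0.12, 0.08 ± 0.14, -0.04 ± 0.17 and -0.04 ± 0.32 in the same contrast, whereas input at Duox1 and Shf was also lower, by -0.77 ± 0.35 and -1.06 ± 0.44. At Firre the ratio was 0.222 (0.164 to 0.297) in WT transgene and 0.236 (0.167 to 0.327) in KO transgene, and 0.904 (0.727 to 1.13) in the line labelled KO control. That contrast rests on this line, because WT control had no more than 1 count, and without it the fitted value turned to 1.07 ± 1.62 and the call ended. Along Rapgef4 (71981215 to 72257474), 23 of the 26 peaks were below 0. As 1 summed region the gene fell by 0.44 ± 0.04 on the log2 scale (edgeR, adjusted p = 7.28e-22), and the 25 peaks not called alone had a median of -0.38, against 0.01 for the 10 other peaks within 100 kb of the peaks of Gm39845 and Rapgef4.

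**Figure D2:**
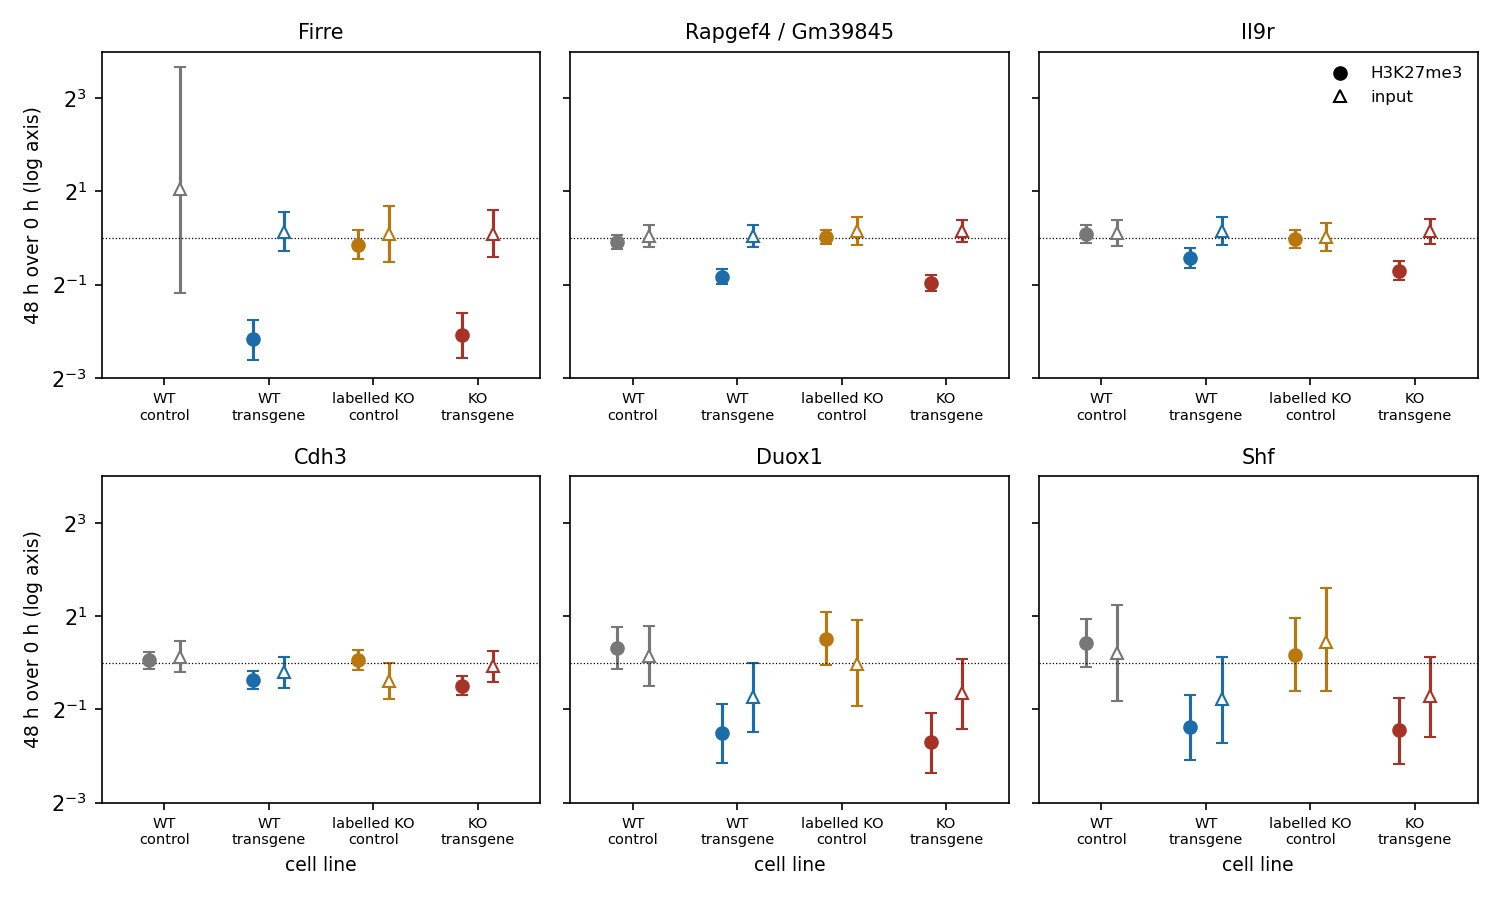
Ratio of counts at 48 h over 0 h, scaled by library, on a log2 axis for the 6 peaks called for induction, in H3K27me3 (filled circles) and input (open triangles), per line with 95% intervals from counting error. H3K27me3 lies below 1 in both transgene lines at all 6 peaks, and the WT control point for Firre H3K27me3 is left out because its counts were 1 and 0.

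**Figure D3:**
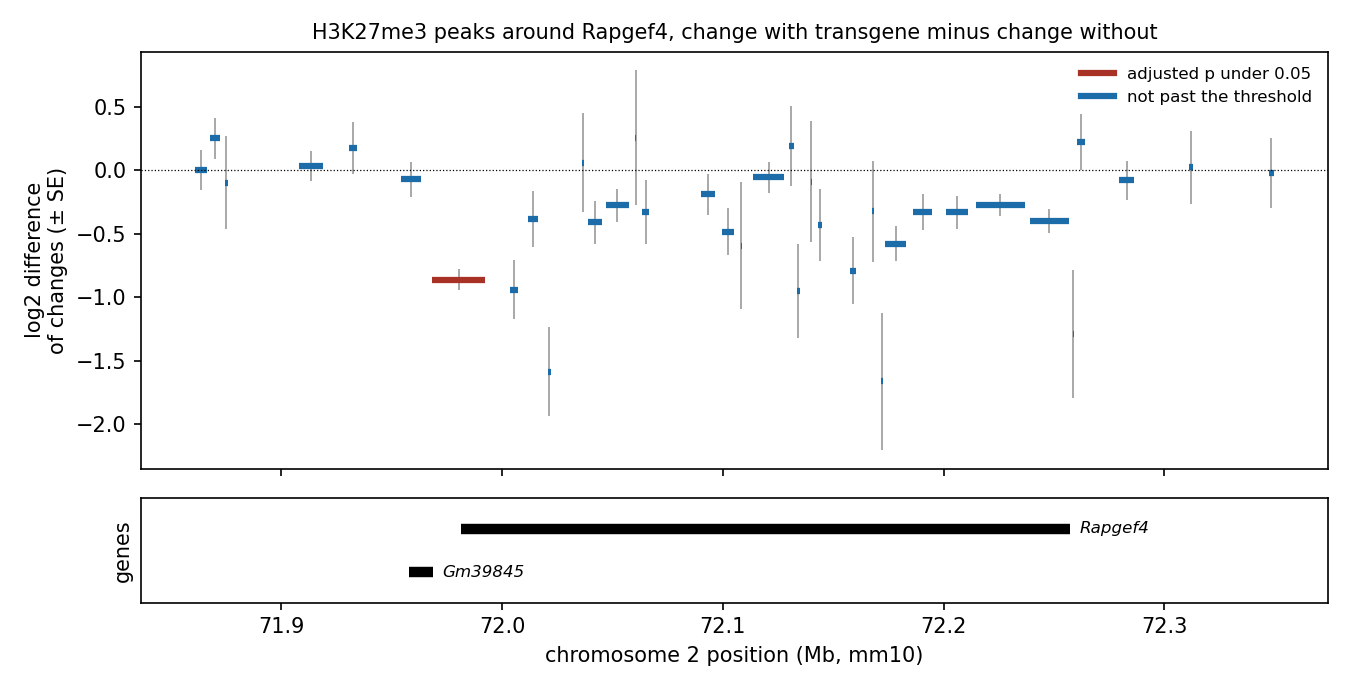
Log2 difference of changes (± SE) for each consensus peak around Rapgef4 on chromosome 2 (mm10), drawn over the peak's extent, with the 2 genes below. Peaks across the gene lie mostly below 0, with 1 past the threshold, and the flanking peaks lie around 0.

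Among 18364 gene regions, 8 fell (Rapgef4, Gm39845 with a window that takes in the Rapgef4 peak, Shf with a window that takes in the Duox1 peak, Firre, Il9r, the neighbouring Snrnp25, Cdh3 and Gm12916) and 1 rose, Rbfox3, which encodes a neuronal splicing factor, by 0.07 ± 0.01. Of 148 regions in the fixed lists only Firre passed over all regions. Adjusted over the list alone, Ascl2, an imprinted trophoblast regulator, also passed, at -0.32 ± 0.09. None of the 6 Hox, 24 neuroectoderm, 24 mesoderm or 14 endoderm regions passed, with cluster values of 0.04 ± 0.02 at HoxA, 0.03 ± 0.01 at HoxB, 0.01 ± 0.02 at HoxC and 0.02 ± 0.02 at HoxD. The list of Firre and its neighbours on chromosome X was lower as a set in camera with the preset correlation (adjusted p = 0.00777) but not with an estimated correlation (adjusted p = 0.797), and without Firre itself, added after the data were seen, it passed with neither (adjusted p = 0.628 and 0.843). No other list passed either. The 6 calls stood beside 5055 peaks at an unadjusted p under 0.05. DESeq2 called 1 peak, lower, limma-voom 4 higher and 7 lower, and edgeR 1 with input as an offset. Leaving out the KO transgene library at 0 h or at 48 h, or the WT control library at 48 h, left 3 calls. In simulated data with these depths, 46 of 100 changed peaks were recovered at a log2 change of 1 and 13 of 100 at 0.5.

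From 0 h to 48 h of doxycycline, irrespective of the transgene, H3K27me3 fell by a small amount at developmental regulators that carried much of it. The Hox clusters fell by 0.12 ± 0.01 (HoxA), 0.10 ± 0.01 (HoxB), 0.08 ± 0.01 (HoxC) and 0.14 ± 0.01 (HoxD) on the log2 scale and were lower in all 4 lines. Input in the same contrast was at -0.01 ± 0.03, -0.02 ± 0.02, 0.00 ± 0.03 and -0.07 ± 0.03, and at -0.05 ± 0.03 for the main block of HoxB genes. Regulators of the nervous system fell with them, among them Neurod1 (-0.21 ± 0.05), Otx1 (-0.18 ± 0.03), Neurog1 (-0.16 ± 0.04), Sox1 (-0.12 ± 0.02) and Pax6 (-0.11 ± 0.02). Mesoderm genes included Tbx18 (-0.22 ± 0.03), Eomes (-0.16 ± 0.04) and Foxc1 (-0.15 ± 0.03), and endoderm genes Foxa1 (-0.13 ± 0.02), Sox17 (-0.11 ± 0.03) and Foxa2 (-0.11 ± 0.02). Each value rests on 4 libraries against 4, matched by line. The offset that follows enrichment, given below, was not applied to gene regions. These values and the list results are thus not separated from the general fall.

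By list, 5 of 6 Hox regions fell over all regions tested and 5 adjusted over the list alone. The counts were 11 and 20 of 24 for neuroectoderm, 8 and 15 of 24 for mesoderm and 4 and 7 of 14 for endoderm regulators, with none higher. Camera placed these 4 lists lower than other regions with an estimated correlation as well (adjusted p = 0.0237 for Hox, 0.0237 for neuroectoderm, 0.0237 for mesoderm and 0.0424 for endoderm). Of the 8 Polycomb regions 4 fell, among them Ezh1, Cbx2 and Bmi1 (-0.10 to -0.11), with an adjusted p = 0.118 for the list with an estimated correlation. Of the trophoblast markers 2 of 8 fell over all regions and 5 over the list alone, led by Tfap2c (-0.26 ± 0.06), with an adjusted p = 0.0604 for the list with an estimated correlation. Firre was the 1 call among the 8 regions of the list of Firre and its neighbours (camera adjusted p = 0.0424 for the list with an estimated correlation, and without Firre itself 0.190, or 0.0434 with the preset correlation). Of 19 imprinted regions 1 fell, Sgce (-0.11 ± 0.03), and 4 over the list alone. Sox17 among primitive endoderm and Otx2 among primed epiblast markers (-0.13 ± 0.03) passed, while none of the pluripotency, housekeeping, germline, X inactivation, Firre contact or fibroblast regions did.

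Of single peaks, 105 fell and 7 rose. Firre (-1.24 ± 0.10) had its fall in the transgene lines, as above. The largest other falls with enough depth and the same direction in all 4 lines were at Mark4 (-0.60 ± 0.13), Ppp4r4 (-0.47 ± 0.11), Pde8a (-0.46 ± 0.10), Npr3 (-0.38 ± 0.07), Foxp1 (-0.38 ± 0.08), Nhs (-0.36 ± 0.09), Vopp1 (-0.31 ± 0.07), Id2 (-0.30 ± 0.07), Lncpint (-0.29 ± 0.07), Kcnma1 (-0.28 ± 0.06) and the peak shared by Lrba and Mab21l2 (-0.27 ± 0.06). Rises under the same rule were at Pakap (0.29 ± 0.07), Clstn3 (0.26 ± 0.05), Sorcs2 (0.25 ± 0.06) and Adamtsl2 (0.25 ± 0.06). The 1030 peaks with the highest ratio over input had a median of -0.06, between -0.07 and -0.06 in the 4 lines, and 79.8% of them lay below 0, against 48.7% of the 51479 with the lowest ratio. An offset per library that follows this ratio, added after the data were seen, left 17 lower and 8 higher peaks. It was run on single peaks only. Most falls were thus no longer called once the trend with enrichment was taken out, and that trend was near equal in the 4 lines. A weaker pulldown at 48 h in all lines would give this, but so would a loss of the mark that follows enrichment. The offset cannot tell them apart, so both stay open. Leaving out any 1 library gave 58 to 67 calls. Without the line as a block no peak passed in edgeR (4046 at an unadjusted p under 0.05), and DESeq2 called 13 peaks and limma-voom 191 with the block. Collection batch was not labelled and cannot be told apart from time. Input showed no call for time (4908 peaks at an unadjusted p under 0.05, edgeR only), but with input as an offset 2 peaks were called and 15 of the named peaks fell short of the threshold.

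The KO lines differed from the WT lines mainly along chromosome 11, where 2926 of 5808 peaks were higher in H3K27me3 by edgeR. The input carried the same difference. Chromosome 11 held 10.5 ± 0.662% of input counts in KO and 8.35 ± 0.109% in WT libraries (SD, n = 4 and 4), a ratio of 1.26, and 10.2 ± 0.675% and 8.10 ± 0.109% of H3K27me3 counts, also a ratio of 1.26 (exact two-sided permutation p = 0.0286 for each, the smallest that 4 against 4 libraries can give; adjusted p = 0.0301 over 20 chromosomes). This test takes both times of a line as separate libraries, and with whole lines exchanged, 2 against 2, the exact permutation p was 0.333 in each assay, the smallest possible. By line, the input share was 8.44% in WT control, 8.25% in WT transgene, 9.97% in KO transgene and 11.1% in the line labelled KO control. The ratio to WT was near uniform along the chromosome, between 1.31 and 1.37 per 10 Mb of input in the line labelled KO control and between 1.17 and 1.21 in KO transgene. The median log2 difference over the peaks of chromosome 11 was 0.34 in H3K27me3 and 0.35 in input. As shares sum to 1, 19 of 20 chromosomes passed. With peaks outside chromosome 11 as denominator, the chromosome 11 ratio was 1.29 in both assays at the same permutation p of 0.0286, and after adjustment no chromosome passed (smallest adjusted p = 0.0952 in H3K27me3 and 0.114 in input).

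**Figure D4:**
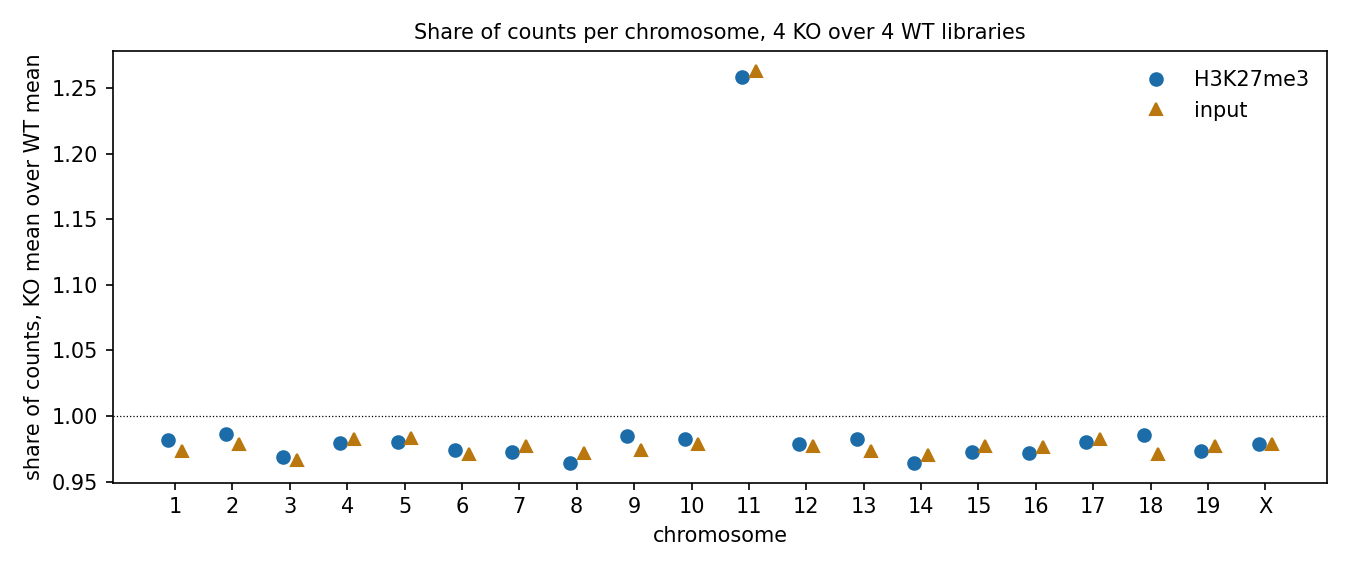
Ratio of the mean share of counts per chromosome, 4 KO over 4 WT libraries, for H3K27me3 (circles) and input (triangles). Chromosome 11 stands at 1.26 in both, and all other chromosomes lie slightly below 1.

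In total, edgeR called 3911 peaks higher and 640 lower in KO, of which 985 and 640 lay off chromosome 11. With total counts in place of TMM the split was 3280 and 1221, and with chromosome 11 left out of the fit, added after the data were seen, 763 and 210. Of the 3911 and 640 peaks, 713 and 71 were called higher than input, and 9 and 0 were at least 2-fold over it. Their median log2 ratio over input was -0.20 and -0.16, relative to the average consensus peak. Among peaks under the naming rule, the largest gain was at a peak inside the HoxB cluster over Gm53 (chromosome 11, 96262540 to 96265181), by 1.72 ± 0.13 with input at 0.18 ± 0.15. Tnrc18 on chromosome 5 (142812403 to 142816957) followed, by 1.29 ± 0.09 with input at -0.09 ± 0.12. The log2 ratio over input was -0.49 at the Gm53 peak and -0.04 at the Tnrc18 peak. Next came 3 peaks in Ntn1, the netrin 1 gene on chromosome 11 (0.84 to 1.03, input 0.24 to 0.42), and peaks in Slc16a6 (0.96 ± 0.14), Tnrc6c (0.93 ± 0.10), Gm11545 (0.90 ± 0.12), Tom1l2 (0.89 ± 0.11) and 4933439C10Rik (0.85 ± 0.14) on that chromosome, and Skida1 on chromosome 2 (0.85 ± 0.14, input 0.08 ± 0.17). The largest losses under the rule were at 3 peaks on the scaffold JH792827.1 (-1.72 ± 0.11, -1.56 ± 0.12 and -1.50 ± 0.15), where input was lower too (-1.27 ± 0.10, -1.20 ± 0.13 and -1.26 ± 0.15). Against the median of the 4 lines, this scaffold stood out only as high in WT transgene (log2 1.67 in input and 2.05 in H3K27me3). These losses thus go with 1 WT line and not with the KO lines. Losses without a matching input change lay in Gm43305 (chromosome 14, 54297167 to 54300657; -0.86 ± 0.13, input 0.03 ± 0.15), in Smc1b with Fam118a (-0.58 ± 0.10), in Tnni3, the cardiac troponin I gene (-0.57 ± 0.10), in Smoc1 (-0.57 ± 0.11) and in Dppa3, a germline and naive pluripotency gene (-0.56 ± 0.11).

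Among the fixed lists, 30 of 148 regions were higher in KO and 3 lower, and 20 and 2 with chromosome 11 left out; total counts gave 25 and 10. HoxB, on chromosome 11, was 0.48 ± 0.04 higher with its input at 0.39 for the main block of genes, HoxC 0.20 ± 0.03 (edgeR, adjusted p = 2.34e-05) and HoxD 0.09 ± 0.03 (edgeR, adjusted p = 0.0318), while HoxA at 0.09 ± 0.03 did not pass (edgeR, adjusted p = 0.0791). With total counts HoxD was at 0.06 ± 0.02 and no longer passed, and with chromosome 11 left out HoxA passed at 0.11 ± 0.03. Adjusted over the list alone, 6 of 6 Hox regions were higher, and 5 over all. Off chromosome 11 these differences lay mainly in 1 pair of lines, as did a shift of the most enriched peaks in general. The 1030 peaks with the highest ratio over input had a median KO over WT value of 0.12 at 0 h and 0.11 at 48 h between the lines labelled control, and of -0.02 and -0.03 between the transgene lines. At the Hox clusters, between the lines labelled control the KO over WT log2 value was 0.27 at HoxA, 0.70 at HoxB, 0.36 at HoxC and 0.22 at HoxD, whereas between the transgene lines it was -0.04, 0.31, 0.09 and 0.00. The difference between the pairs passed at all 4 clusters (background by transgene term -0.30 ± 0.02 at HoxA and -0.38 ± 0.02, -0.30 ± 0.03 and -0.21 ± 0.02 at the main peak of HoxB, HoxC and HoxD). Each combination is 1 line, so these SEs rest on its 0 h and 48 h libraries and do not measure differences between clones.

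**Figure D5:**
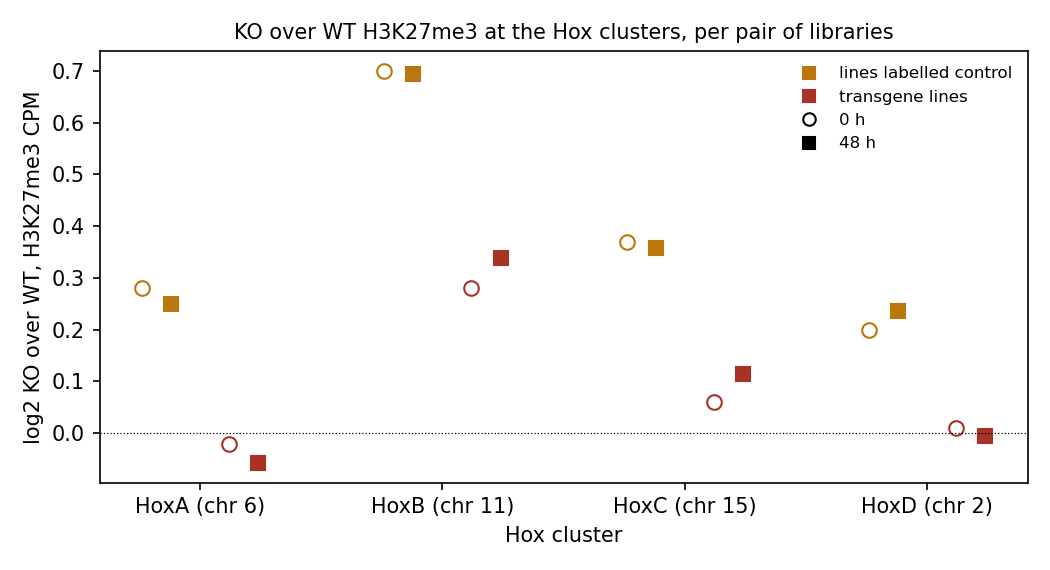
Log2 ratio of KO over WT H3K27me3 CPM at the 4 Hox clusters, for the pair of lines labelled control and the pair of transgene lines at 0 h (open circles) and 48 h (filled squares), 1 pair of libraries per point. At each cluster the control pair lies above the transgene pair.

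Of the other lists, 5 of 8 Polycomb regions were higher, among them Kdm6b, Ezh1 and Cbx2 on chromosome 11 (0.32 to 0.48 with input 0.38 to 0.49) and Kdm2b on chromosome 5 (0.24 ± 0.08). Neuroectoderm had 4 of 24 higher (Gbx2, Otx1, Dlx2 and Sox1) and 5 adjusted over the list alone, mesoderm 4 of 24 (Hand1, Meox1, Tbx18 and Eomes) and 4, and endoderm 3 of 14 (among them Sox9 and Cdx1) and 3. Otx1, Hand1, Meox1 and Sox9 lie on chromosome 11. Fibroblast markers had 2 of 7 higher, Col1a1 on chromosome 11 and Pdgfrb, trophoblast markers 3 of 8 (Hand1, Krt8 and Eomes) and 5 adjusted over the list alone, primitive endoderm markers 2 of 8 (Lama1 and Pdgfra), imprinted genes 3 of 19 (Grb10, Gnas and Sgce) and X inactivation genes 1 of 4, Huwe1 (0.40 ± 0.10). Passing as lower were Dppa3 in the pluripotency list (-0.46 ± 0.07), Mbnl3 among the Firre neighbours (-0.34 ± 0.10) and Ypel4 among the Firre contacts (-0.27 ± 0.08). Airn, Dcn, Dab2 and Tfap2c were lower adjusted over the list alone only. With windows at the gene ends Gnas turned to -0.34 and Airn to 0.18. No list passed camera with an estimated correlation (smallest adjusted p = 0.680), and none of the primed epiblast, germline or housekeeping regions passed. Leaving out the line labelled KO control, added after the data were seen, gave 1445 higher (1216 on chromosome 11) and 221 lower peaks. That fit compares KO transgene with WT transgene alone, 1 line against 1, and 1373 and 110 of its calls were shared with the main fit. DESeq2 called 1680 in all, and 97 passed with input as an offset. Lines were not replicated within a genotype, so differences between clones cannot be told apart from the genotype.

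Lines labelled with the transgene were compared with lines labelled without it, both times pooled. The latter include the line labelled KO control, whose Firre input was 11.1 times the chromosome X mean. The contrast is thus not between lines with and without extra Firre sequence. In it, 30 peaks were higher and 47 lower. Of those lower, 29 lay on chromosome 11, including Ntn1 (-0.65 ± 0.14, input -0.13 ± 0.17), Tnrc6c (-0.46 ± 0.10, input -0.27 ± 0.13), Gas7 (-0.42 ± 0.10, input -0.20 ± 0.13) and Map2k6 (-0.37 ± 0.08, input -0.02 ± 0.11). The chromosome 11 share of input was also lower in KO transgene than in the line labelled KO control. Others lay in Hdac7 (chromosome 15, 97799600 to 97802142; -0.61 ± 0.13), Gm31458 (-0.58 ± 0.12), Pakap (-0.47 ± 0.10) and Dapk1 (-0.40 ± 0.08). Higher were the first peak of scaffold JH792827.1 (1.48 ± 0.11, input 1.28 ± 0.10), Gm43305 (0.53 ± 0.12), Shroom3 (0.43 ± 0.09), Atcay (0.40 ± 0.09), Slc5a1 (0.38 ± 0.09) and Zmat4 (0.37 ± 0.08). The scaffold stood out in input only as high in WT transgene. Also higher were 3 peaks over CK137956 and Csmd2 on chromosome 4 (127965565 to 128146436; 0.33 to 0.36), where input was higher too (0.23 to 0.47). With input as an offset CK137956 turned to -0.11 and the first Csmd2 peak to -0.01. In the lists, the imprinted genes Kcnq1ot1 (0.12 ± 0.03) and Cdkn1c (0.13 ± 0.03) were higher, and Plagl1 (-0.56 ± 0.14) and Col1a1 (-0.18 ± 0.05) were lower. Adjusted over the list alone, Dppa3 was also higher, and regions including Nnat, Cdx1, Krt8 and Cbx2 were also lower. No list passed camera with an estimated correlation (smallest adjusted p = 0.637). No Hox, neuroectoderm, mesoderm, housekeeping, germline, X inactivation, Firre neighbour, Firre contact, primitive endoderm or primed epiblast region passed. The pooled values average backgrounds that differed. The 1030 peaks with the highest ratio over input had transgene medians of 0.11 at 0 h and 0.12 at 48 h in WT, and of -0.03 at both times in KO. The background by transgene term was called at 454 peaks, among them the main peak of each Hox cluster. DESeq2 called 1 peak and limma-voom 31 higher and 62 lower. Leaving out the KO control library at 48 h left 17 calls, at 0 h 21, and the KO transgene library at 48 h 20 and at 0 h 34. The split depended on scaling, with 33 higher and 25 lower under TMM from background peaks and 44 and 162 with the offset that follows enrichment. Without the line labelled KO control it was 200 and 32. That fit compares WT transgene with WT control alone, 1 line against 1, with the 2 times as the only repeats. Of its calls, 10 higher and 7 lower were also called in the main fit.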

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

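All tests of explanations in this part were chosen only after the results they address had been seen.

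The H3K27me3 losses on induction at Firre, Rapgef4, Il9r and Cdh3 had a median of -0.73. The input over these peaks had a median of -0.0164 in the same contrast. These 4 peaks were set apart from Duox1 and Shf after the input was seen, so that median carries no weight by itself. Peak by peak, input lay above H3K27me3 by at least 2.17 standard errors. For these peaks this argues against fewer copies or lower input coverage at 48 h as the whole of the loss. A weaker pulldown at 48 h in the transgene lines would lower the most enriched peaks too, but the 1030 with the highest ratio over input had a median of 0.00889. At Duox1 and Shf, judged as a pair, the input median was -0.92 beside -1.86 in H3K27me3, and the smallest distance was 1.26 standard errors, at Shf. Lower input coverage thus stays open there as part of the change. Only 3 pairings of the 4 lines exist, too few for a share under 0.05; the real one gave 6 calls and the highest other 1. A local loss of H3K27me3 with Firre induction may explain the 3 genes other than Firre, an untested hypothesis. That hypothesis is limited by low enrichment, since only 1 of the 6 peaks was called higher than input, measured against the average consensus peak. The change at Firre rests on the line labelled KO control, and its counts go with extra Firre sequence.

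More H3K27me3 on chromosome 11 in the KO lines went with more input. The median log2 difference was 0.35 in input and 0.34 in H3K27me3, and the difference between them was -0.00425, which argues against more H3K27me3 per copy. Extra copies of chromosome 11 in a part of the cells could give these values, with a higher share in the line labelled KO control than in KO transgene. The input odds relative to the WT mean were 1.37 and 1.22 in these lines. Both lie below the value for 1 extra copy in every cell of a diploid line, which argues against that. Ploidy was not measured, and whether extra copies came with the genotype or with the clones was not tested. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many calls (3883 without covariates, highest other 1), and 1 gave as many list regions (23, highest other 0), but only 3 splits keep the libraries of a line together, too few for a share under 0.05.

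The line labelled KO control had 11.1 times the chromosome X mean of input over the Firre peak, and its H3K27me3 counts there were 164 and 177. Mixing with the KO transgene line would bring its chromosome 11 share of 9.97%, but the share was 11.1%, outside that line's 95% Wilson interval. An exchange of labels between these lines would leave the KO transgene libraries without extra Firre sequence, but they had 10.7 times the mean. Transgene copies that do not respond to doxycycline are a candidate explanation. A drop as in the transgene lines would have gone against it, but the H3K27me3 ratio of 48 h over 0 h was 0.904 (0.727 to 1.13). This ratio restates the counts that raised the question, so it gives no separate support. A wrong genotype label stays open too.

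The KO over WT difference in H3K27me3 was not the same in the control and the transgene lines, where each combination is 1 line and differences between clones cannot be told apart from background and transgene. The interaction term was called at 454 peaks, 45 higher and 409 lower, of which 190 lower were on chromosome 11, and included HoxA (-0.30), HoxB (-0.38), HoxC (-0.30) and HoxD (-0.21), each a difference between the KO effects in the control and in the transgene lines. The KO and WT backgrounds differed in their change over time at 1 peak, Firre (1.34 ± 0.24; edgeR, adjusted p = 0.00129), a value that involves the line labelled KO control. In input, 1925 peaks were called between KO and WT (1855 higher and 70 lower) and 6 between transgene lines and others (5 higher and 1 lower). A scan of 9162 windows of input stood out at 3. Scaffold JH792827.1 was high in WT transgene (log2 1.67 in input and 2.05 in H3K27me3), chromosome 11 from 17600001 to 17800000 was high in the line labelled KO control (0.56 and 0.30), and chromosome 4 from 127800001 to 128000000, over CK137956 and Csmd2, was low in that line (-0.59 and -0.65). The input library of KO control at 0 h had 3340654 counts, far from the next of 5870865 among 8 inputs (gap over range 0.871) and of 6029434 among the 4 KO inputs (0.928). These were 2 of 16 groups tested, where chance marks about 1 group in 20. Both flags rest on the same count in nested groups and are thus 1 observation.

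For time, 8 swaps within lines exist, too few for a share under 0.05; the real times gave 112 calls and 35 list regions, the highest other swap 4 and 1, each with 1 swap as large. For transgene, 2 of 33 splits gave as many peaks (real 77, highest other 79, the split that follows the background by transgene grouping) and 4 as many list regions (real 4, highest other 11), and only 2 of these splits keep lines whole, too few for a share under 0.05. For H3K27me3 against input, 1 of 24 exchanges, the real one, gave as many calls (45002, highest other 6787), but only 8 exchanges keep lines whole, too few for a share under 0.05 (highest other 0).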

How the results depend on the processing

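Chosen only after the results were seen were the tests with a robust dispersion, an offset that follows enrichment, windows at the gene ends, chromosome 11 left out, peaks outside chromosome 11 as denominator, whole lines exchanged, the Firre neighbour list without Firre, and the line labelled KO control left out. Among values of single peaks and list regions, 1003 kept direction and side of the threshold under alternatives fixed before the data were examined, 388 fell short of the threshold and 4 turned; under those added later the counts were 396, 76 and 3, and 1 newly passed. The cause was not tested unless stated.

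The 6 induction calls became 1 with DESeq2, 11 with limma-voom, 1 with input as an offset and 0 of 127 peaks at least 2-fold over input, a set that held none of the 6 (4 at an unadjusted p under 0.05, edgeR). Leaving out 1 library gave 3 to 5. The Firre value turned to 1.07 without the line labelled KO control, and over the libraries left out singly it ran from -2.01 to 1.05, turning without the 0 h (1.05) or 48 h (1.02) library of that line, because WT control had no more than 1 count. No list region passed with windows at the gene ends, where the count became 0 (edgeR).

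The 112 time calls became 13 with DESeq2, 191 with limma-voom and 2 with input as an offset. Among peaks at least 2-fold over input 3 passed, 2 higher and 1 lower, and the median of that set was 0.006. Scaling within this set of 127 centres it near 0, so this fit cannot show a fall shared by the set. In the main fit 16 of the 105 falls and 0 of the 7 rises lay in such peaks. The 1030 peaks with the highest ratio over input had a median of -0.06 there. The 112 calls became 25 with the offset that follows enrichment and 0 without the line as a block (4046 at an unadjusted p under 0.05, edgeR). They became 67 without the line labelled KO control, where fewer libraries were tested. Leaving out 1 library gave 58 to 67.

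The 4551 calls between KO and WT became 1680 with DESeq2, 97 with input as an offset, 4 among peaks at least 2-fold over input, 1920 with the 0 h libraries alone, 973 with chromosome 11 left out and 1666 without the line labelled KO control. The fit without that line compares KO transgene with WT transgene alone. Leaving out 1 library gave 3146 to 4234. With windows at the gene ends Airn turned to 0.18 and Gnas to -0.34. With peaks outside chromosome 11 as denominator, 0 chromosomes passed in H3K27me3 and 0 in input (exact permutation test) after adjustment, while the chromosome 11 ratio was 1.29 in both, at the same permutation p of 0.0286. With whole lines exchanged that ratio was 1.26 in H3K27me3 and 1.26 in input, with an exact permutation p of 0.333 for each, the smallest that 2 lines against 2 can give.

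The 77 transgene calls became 135 with total counts, 1 with DESeq2, 128 with a mean count of at least 50, 1 with input as an offset, 0 among peaks at least 2-fold over input, a set that held none of the 77 (9 at an unadjusted p under 0.05, edgeR), 206 with the offset that follows enrichment, 5 with the 0 h libraries alone, 43 with chromosome 11 left out and 232 without the line labelled KO control. The fit without that line compares WT transgene with WT control alone, and only 10 higher and 7 lower of its calls were among the 77. Leaving out 1 library gave 17 to 107. With input as an offset CK137956 turned to -0.11 and the first Csmd2 peak to -0.0110. List regions became 2 with chromosome 11 left out.

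Calls of H3K27me3 against input became 24321 with TMM and 135 at 2-fold or more, and the 102957 consensus peaks became 127 at least 2-fold over input, by construction. Leaving out 1 condition gave 40274 to 42541. No paired analysis was possible because the replicate number is 1 in every group, except by line, which was part of the design for time and induction, and by condition, in the comparison with input. Where leaving out a library left a condition empty, the spread came from the remaining libraries. In the time and induction fits, with line as a block, the other library of that line then adds nothing. Leaving out 1 library there leaves out its whole line in effect. Peaks had a median of 43 to 63 counts in H3K27me3.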
